A study of Mus musculus with 4 samples.

How the data were processed

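Droplet single-cell RNA sequencing with the 10x Genomics system was carried out on cells of the retinal pigment epithelium (RPE) and choroid, the pigmented layer behind the photoreceptors and the vascular layer beneath it. The 4 libraries came from wild-type mice and Vldlr-/- mice (knockout, lacking the very low density lipoprotein receptor) at ages of 1 month and 2 months, with 1 library per group. Per the labels' protocols, the neural retina was lifted off, the remaining tissue was digested with collagenase, dispase and trypsin, and dead cells were removed before loading. The number of animals pooled into each library is not given in the sources used here.

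The deposited values were raw UMI counts (unique molecules) per gene and cell barcode, written as whole numbers with no normalization, per the file headers. The headers name Cell Ranger 6.0.2 for both 1-month libraries and 7.0.1 for both 2-month libraries. The submitters' processing notes name Cell Ranger 3.0, Seurat 4.0 and the mm9 build instead. Whether reads in introns were counted is not given in the sources used here. Of the 32285 gene identifiers, 32235 matched the GENCODE M21 annotation of GRCm38, which gave the coordinates printed. Age and software version separated the libraries in the same way, so differences between the ages cannot be parted from differences in counting. The knockout and wild-type libraries of 1 age shared a version.

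Barcodes with at least 300 genes and at most 30% mitochondrial UMIs were kept, which left 1549 of 1696 (wild type, 1 month), 1819 of 2073 (knockout, 1 month), 2047 of 2540 (wild type, 2 months) and 1140 of 1634 (knockout, 2 months). Scrublet, run per library through scanpy 1.11.5, marked 14 of 6555 barcodes (0.214%), too few for doublet removal to count as having worked. These were removed, and an alternative removed the 89 with the highest scores. The remaining 6541 cells were scaled to 10000 counts per cell, and 2000 variable genes, scaled to unit variance, gave 30 principal components. A graph of 15 neighbours was clustered with the Leiden method at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9) into 30 clusters, with no integration across libraries. Clusters were named "X-like" from marker genes fixed in advance. Of these, 4 clusters stayed unnamed. An added rule left clusters led by Gpx3, Penk, Optc and Crhbp unnamed, and it was written after the clusters were seen. The unscaled version of the principal components was also tried after the RPE-like shares under a 15% mitochondrial limit had been seen. The scaled version, the first one written, was kept as the main setting.

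Raw counts were summed per library and cell class and scaled to a total of 1000000 per library (CPM). With 1 library per group no group has a replicate error, and no test was run. An additive model of genotype and age, which would leave 1 residual degree of freedom, was not fitted. Sums carry exact Poisson 95% intervals and shares carry exact Clopper-Pearson 95% intervals. Both cover counting error only. The log2 ratio of knockout to wild type was computed from CPM after adding 0.5 counts, for genes with at least 30 UMIs in the libraries compared. For 33 gene lists, the median log2 ratio was set beside the medians of 10000 random lists of equal size matched on mean expression. Lists with at least 4 measured members were used. The percentile among those lists is a description of these libraries, not a test of genotype. Besides RPE-like cells, the endothelial, fibroblast, mural, melanocyte and macrophage classes were compared where each library held at least 30 cells. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

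The markers, gene lists, filters, comparisons, the rule for named genes and most alternatives were fixed before the data were examined. The rule took RPE genes with at least 30 UMIs over the 4 libraries that were at least 2-fold apart in the same direction at both ages. Their CPM had to reach at least 0.25 of the CPM in every other class with at least 30 cells, as a guard against free RNA. The 10 genes per direction with the largest smaller log2 ratio were named, with 3 more per direction and age by size, and 2 members of each list described. Fibroblast-like and macrophage-like cells took 4 per direction. Vldlr, sex-linked genes and markers were named where they bore on a check.

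The calculation was tested on simulated counts for 11903 genes of the RPE-like comparison. Being 2-fold apart at both ages was recovered for 64.0% of genes raised by 2.5-fold and 92.0% of those raised by 4-fold. For genes lowered to 0.4 or 0.25 of their level the figures were 55.3% and 68.0%, and 0.0342% of unchanged genes were called. In the 2-month comparison of 11829 genes, 3.5% of unshifted lists lay outside the central 95% of random lists. Simulated libraries were drawn from the pooled counts of both genotypes at each age, with counting error alone besides the set changes. No differences between animals, preparations or cell mixes were simulated, so these figures are not error rates of the real comparison.

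Alternatives covered the mitochondrial limit, the minimum number of genes, doublets, clustering resolution, scaling, weighting of cells, depth, free RNA, count minimum and added count. Several more were added after the data were seen. They separated RPE-like clusters by Malat1 (over or under 5000 CPM), left out Gm42418 or clusters with over 20% of it, required 30 UMIs in each pair of libraries, or matched random lists on exon length as well. For the depth setting each RPE-like cell was thinned to 2000 UMIs, which left out 111, 80, 71 and 19 cells of wild type and knockout at 1 month and wild type and knockout at 2 months. For the free RNA setting, the library profile subtracted made up 6.90%, 7.17%, 3.25% and 0.949% of RPE-like UMIs in that order.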

Results

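The 4 libraries held 11194301 UMIs (wild type, 1 month), 12022513 (knockout, 1 month), 23070271 (wild type, 2 months) and 16292472 (knockout, 2 months). The median kept barcode carried 6036, 5084, 8021 and 9029 UMIs in that order. The series title concerns mitochondrial energetics of the RPE and subretinal fibrosis in neovascular macular degeneration. The comparisons therefore asked how RPE-like and choroidal cells of Vldlr-/- mice differed from wild-type cells at each age. Each group was 1 library, so no difference at a single age has a replicate check.

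Vldlr, the targeted gene (ENSMUSG00000024924, GRCm38 chromosome 19, 27216484 to 27254231, plus strand), was lower in knockout RPE-like cells at both ages. At 1 month 78 UMIs (131 CPM) were counted in wild-type and 4 (10.7 CPM) in knockout RPE-like cells, a log2 ratio of -3.45 (95% interval -5.53 to -2.20). At 2 months the counts were 2785 (177 CPM) and 218 (27.2 CPM), a log2 ratio of -2.70 (-2.91 to -2.50). Rod-like cells, the photoreceptors of dim light, kept much of their Vldlr signal, with 297 CPM in wild type and 209 CPM in knockout at 1 month (log2 ratio -0.51) and 297 and 249 CPM at 2 months (-0.25, with an interval that includes 0). Over all kept cells of the 1-month libraries, where rod-like cells were more numerous in the knockout, the log2 ratio was 0.64, and at 2 months it was -2.06. The deleted part of the gene is not given in the sources used here, and tags from a 3′ end outside it would check nothing. Xist, expressed from the inactive X chromosome, stood at 330 and 649 CPM in wild type and knockout at 1 month and at 97.1 and 290 CPM at 2 months. Y-linked Ddx3y was counted in each library too (39.5, 20.9, 64.2 and 43.3 CPM in the same order). Over all kept cells these levels do not give the proportion of each sex, since Malat1-poor barcodes, which held little Xist, differed in share between the libraries. In fibroblast-like cells, with at most 2.58% of barcodes under 1000 CPM of Malat1, Xist was higher in the knockout at both ages too. With Ddx3y lower in the knockout at both ages, a different mix of the sexes in knockout and wild-type libraries stays open.

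RPE-like cells made up a smaller share of the knockout than of the wild-type library at both ages. The shares were 14.9% (13.2 to 16.8) in wild type and 8.70% (7.44 to 10.1) in knockout at 1 month, and 69.1% (67.1 to 71.1) and 45.8% (42.9 to 48.8) at 2 months. Fibroblast-like cells, the collagen-producing stromal cells, went the other way, with 16.7% and 21.4% at 1 month and 5.86% and 13.8% at 2 months. Endothelial-like cells, which line blood vessels, were 0.324% and 1.38% at 1 month (5 and 25 cells) and 3.81% and 8.63% at 2 months (78 and 98 cells). Macrophage-like cells made up 1.94% and 1.87% at 1 month and 2.74% (2.07 to 3.54) and 4.85% (3.67 to 6.26) at 2 months. Rod-like cells were 10.9% of wild-type and 26.6% of knockout cells at 1 month, but 4.74% and 4.23% at 2 months. B-like lymphocytes held 16.7% and 14.6% at 1 month and 0.244% and 0.617% at 2 months, and T or NK-like ones 21.0% (19.0 to 23.1) and 10.4% (9.04 to 11.9) at 1 month and 0.537% and 1.23% at 2 months. Dissection, digestion and dead cell removal set these shares as well as the tissue does, and a share falls when any other class is larger. With at least 1000 genes required per barcode, the 1-month RPE-like shares were 6.65% and 3.80%. Red blood cell-like barcodes were 0.454% of wild-type and 0.826% of knockout cells at 1 month, and 2.74% and 7.84% at 2 months. Their cluster also had the RPE genes Ttr, Rgr and Rpe65 among its leading genes. Any RPE barcodes in it were not counted as RPE-like.

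**Figure D1:**
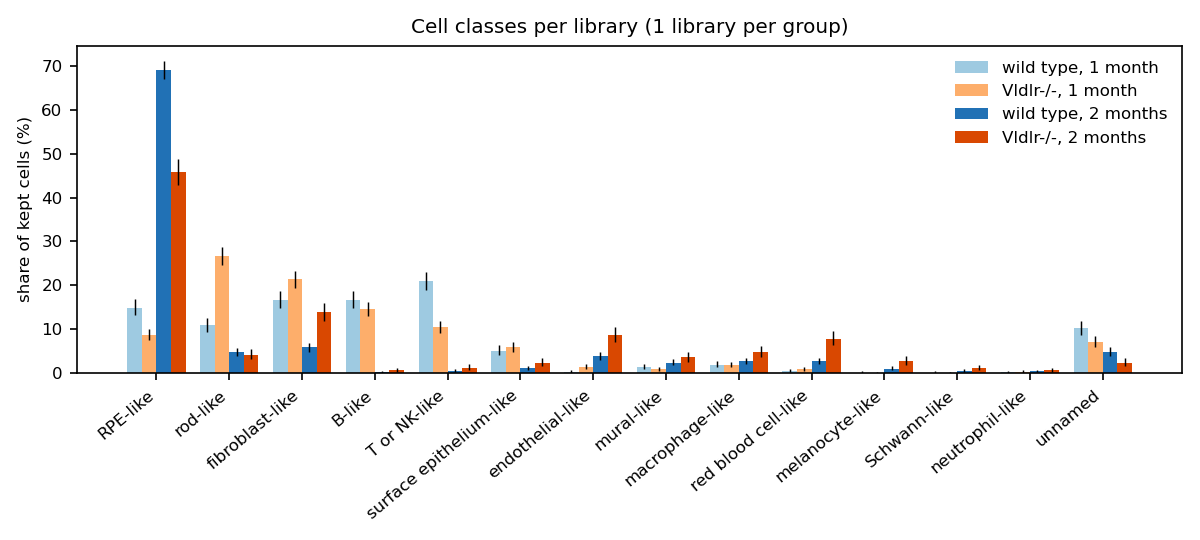
Share of kept cells (percent) in each cell class, with 1 bar per library and exact 95% binomial intervals that cover counting error only. RPE-like cells are 14.9% and 8.70% of the wild-type and knockout libraries at 1 month and 69.1% and 45.8% at 2 months.

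In RPE-like cells, nuclear genes of the mitochondrial respiratory chain had lower values in the knockout at both ages. All 10 genes listed for complex III, which passes electrons to cytochrome c, were lower at 1 month (median log2 ratio -0.39, percentile 0.15 among random lists) and at 2 months (-0.23, percentile 0.06). That list includes Cycs, the gene of cytochrome c itself. Of complex V, the ATP synthase, 15 of 16 genes were lower at 1 month (-0.29, percentile 0.33) and 16 of 16 at 2 months (-0.22, percentile 0.01). Complex IV, cytochrome c oxidase, had 10 of 12 genes lower at 1 month (-0.30, percentile 0.53) and 12 of 13 at 2 months (-0.18, percentile 0.61), but with cells thinned to equal depth the 1-month median was -0.12, inside the central 95% (percentile 27.9). Examples were Cox5a (log2 ratio -0.81 at 1 month and -0.18 at 2 months), Uqcr10 (-0.55 and -0.26), Cyc1 (-0.51 and -0.35), Atp5g2 (-0.64 and -0.17) and Atp5e (-0.53 and -0.20). Cox7a1 went the other way at 2 months (0.70).

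Complex I had 29 of 37 genes lower at 1 month (median -0.15, percentile 7.31) and 35 of 37 at 2 months (-0.12, percentile 0.775). The 4 genes of complex II were lower at both ages (-0.23, percentile 16.6, and -0.21, percentile 1.89). The 13 genes encoded by mitochondrial DNA stayed inside the central 95% of random lists (-0.08, percentile 57.3, and -0.07, percentile 30.7). Tricarboxylic acid cycle genes had medians of -0.20 (percentile 4.53) and -0.19 (percentile 0.00, 15 of 18 lower). Dlat, a pyruvate dehydrogenase subunit, was at -1.13 (36 and 10 UMIs) and -0.11. Fatty acid oxidation genes had a median of -0.46 at 1 month (15 of 19 lower, percentile 0.00) and -0.07 at 2 months (20 of 26 lower, percentile 3.6). Cpt2, which returns acyl groups to coenzyme A inside mitochondria, was at -1.30 (25 and 6 UMIs) and -0.20. Acads, a short-chain acyl-CoA dehydrogenase, was at -1.25 (28 and 7 UMIs) and -0.16. Dlat, Cpt2 and Acads were named for the size of their ratios, and their 1-month ratios rested on few counts. Glycolysis genes had medians of 0.04 at both ages, inside the central 95%.

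These values came with differences in the RPE-like barcodes themselves. Cells of 1 Malat1-rich cluster were 7.56% of wild-type and 20.4% of knockout RPE-like cells at 2 months (107 and 106 cells). At 1 month that cluster held 0 of 230 and 0 of 158, with upper 95% limits of 1.59% and 2.31% for its share. Clusters were made without integration, and 1-month RPE-like barcodes were shallower, with medians of 2082 and 1961 UMIs. Of these barcodes, 80.0% in wild type and 74.7% in knockout were under 1000 CPM of Malat1. The rest, at or above it, lay in the other clusters, and the 1-month values were not separated by Malat1. Malat1 is a long RNA kept in the nucleus, and the other RPE-like clusters carried little of it. These other clusters differed in share too. At 2 months cluster 25, led by Cox8b, Pmel and Dct, held 46 wild-type and 2 knockout cells, and cluster 0 held 38.9% and 28.8% of RPE-like cells. At 1 month cluster 2 held 68.7% and 57.0%, and cluster 1 held 28.3% and 36.7%. The mix of these clusters was not held fixed. Within the Malat1-rich cells the medians of complexes I, III, IV and V were 0.08, -0.04, -0.02 and 0.01, and that of mitochondrially encoded genes was -0.69 with 13 of 13 lower. Markers of rod cells stood at 345 CPM in wild-type and 1234 CPM in knockout RPE-like cells at 1 month and at 73.1 and 40.0 CPM at 2 months. Against random lists matched on exon length as well, complex I moved to percentiles 24.6 and 4.21, while complex III stayed at 0.33 and 0.15. Cytosolic ribosomal protein genes, which are short and abundant too, had medians of -0.16 at 1 month (70 of 80 lower) and 0.02 at 2 months.

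**Figure D2:**
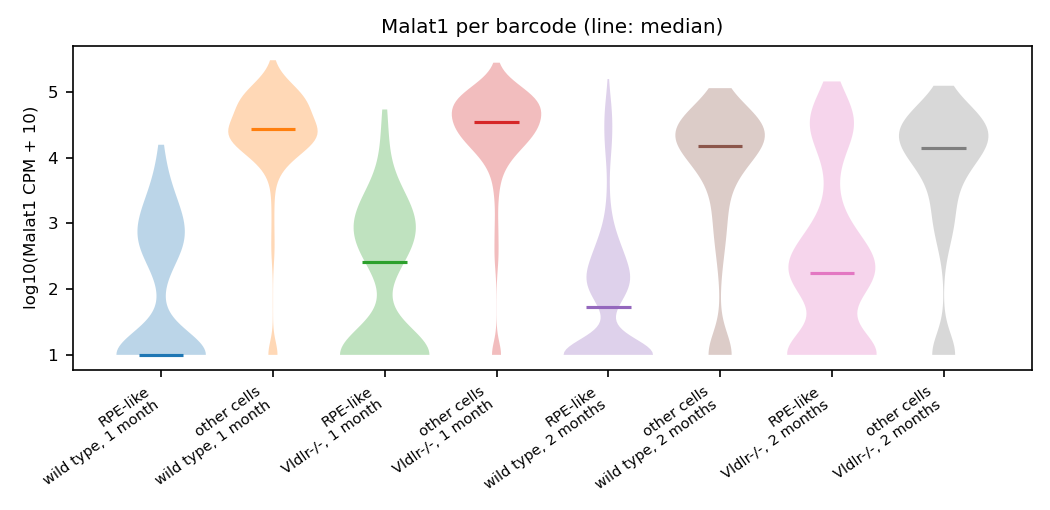
Malat1 in each kept barcode as log10 of CPM plus 10, for RPE-like and other cells of each library, where the width shows the density of barcodes and the line the median. Most RPE-like barcodes lie far below the other cells, and a second group of RPE-like barcodes at the level of the other cells appears at 2 months.

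**Figure D3:**
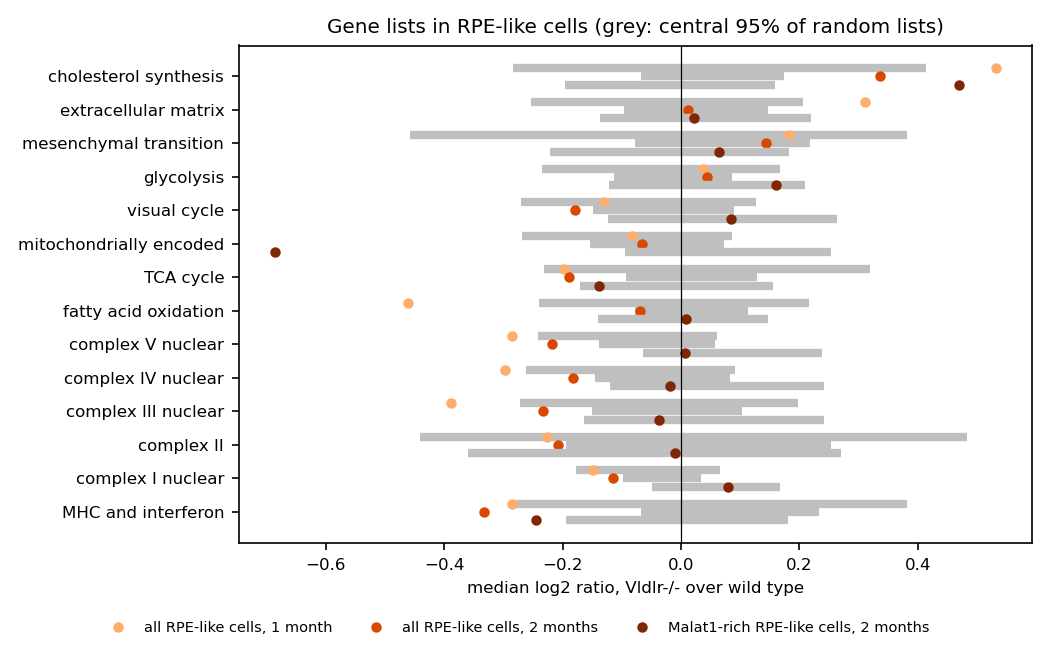
Median log2 ratio of knockout to wild type for gene lists in RPE-like cells, with 1 point per list and cell group and grey bars for the central 95% of random lists matched on expression. Complex III lies at -0.39 at 1 month and -0.23 at 2 months, but at -0.04 in Malat1-rich cells, where cholesterol synthesis lies at 0.47.

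Cholesterol synthesis genes were higher in knockout RPE-like cells, with a median of 0.53 at 1 month (9 of 13 higher, percentile 99.6) and 0.34 at 2 months (18 of 20 higher, percentile 100). Sqle, squalene epoxidase, was at 1.48 and 1.30, and Fdps, which makes farnesyl diphosphate, at 1.13 and 0.72. The list of antigen presentation and interferon genes had a median of -0.28 at 1 month (percentile 2.31), where members went both ways (6 of 10 lower). At 2 months it was at -0.33 (16 of 22 lower, percentile 0.00). Cd74, the MHC class II invariant chain, was at 0.46 at 1 month and -2.11 at 2 months, and Ifit1, an interferon-induced gene, at -3.25 at 2 months. Macrophage activation genes, which mark another class, were lower at 2 months in Malat1-poor (-0.44, percentile 0.06) and Malat1-rich cells (-0.70, percentile 0.00), though at -0.08 (percentile 8.42) in RPE-like cells as a whole. Wnt pathway genes had medians of 0.44 (percentile 98.5) and 0.23 (percentile 99.4), with Sfrp5, a secreted Wnt inhibitor, at 1.05 and 0.94. The 2-month Wnt median was 0.07 without the Malat1-rich cells and 0.01 within them. Visual cycle genes, which regenerate the chromophore of the photopigment, were lower at 2 months (-0.18, 10 of 12 lower, percentile 0.78) and inside the central 95% at 1 month (-0.13). After subtraction of free RNA the 1-month antigen presentation median turned to 0.24. Without that subtraction the 2-month visual cycle medians were 0.08 in Malat1-rich and -0.18 in Malat1-poor cells, both inside the central 95% (percentiles 38.7 and 13.2). The 1-month cholesterol synthesis median was 0.12, inside the central 95% (percentile 57.6), without the clusters rich in Gm42418, a locus that collects ribosomal RNA.

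Lists tied to fibrosis gave no shared picture in RPE-like cells. Extracellular matrix genes had a median of 0.31 at 1 month (12 of 13 higher, percentile 99.4) and 0.01 at 2 months (12 of 23 higher, percentile 45.2). Mesenchymal transition genes lay inside the central 95% at both ages (0.18 and 0.14), but above it at 2 months after subtraction of free RNA (0.34, percentile 99.6), and Vim, an intermediate filament gene, was at 0.02 and 1.12. RPE identity genes had medians of 0.33 (percentile 100, but a median of 0.09 with cells thinned to equal depth) and 0.03 (percentile 92.2), and Pmel, a melanosome gene, was at 0.88 and -0.72. Integrated and endoplasmic reticulum stress genes were at 0.42 (percentile 99.3) and -0.08 (percentile 4.63). Of 26 lists measured at 1 month, 5 lay below and 5 above the central 95%, and of 33 at 2 months, 8 below and 2 above. Random lists would put 1.30 and 1.65 outside.

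Among single RPE-like genes, Trnp1 and Cdhr1 were higher and Pttg1, Acadsb and Arl6ip1 lower in the knockout at both ages. Pttg1, the securin gene (chromosome 11, 43420250 to 43426251), had 91 UMIs in wild type and 3 in knockout at 1 month (log2 ratio -4.04, interval -6.56 to -2.66) and 1374 and 7 at 2 months (-6.55, interval -7.96 to -5.60). Trnp1, a nuclear protein gene studied in cortical progenitors (chromosome 4, 133491100 to 133498550), had 1 and 35 UMIs and then 60 and 697 (5.24, interval 3.23 to 11.1, and 4.50, interval 4.13 to 4.92). Cdhr1, a photoreceptor cadherin gene, had 38 and 222 UMIs and then 1281 and 3718 (3.20 and 2.51). Acadsb, an acyl-CoA dehydrogenase of branched-chain substrates, was at -2.89 and -2.70. Arl6ip1, a membrane-shaping gene of the endoplasmic reticulum, stood at 5998 CPM in wild type and 1695 in knockout at 1 month (-1.82) and at 4609 and 1215 CPM at 2 months (-1.92). Scd1, a fatty acid desaturase, was at 3.07 and 2.64, and Serpina3n, a serine protease inhibitor induced in inflammation, at 4.04 and 5.00, from 1 and 15 UMIs at 1 month.

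The rule was met by 51 higher and 23 lower genes, and the rest of the 10 named per direction rested on few 1-month counts. Lrit1 had 3 UMIs in wild type and 26 in knockout, and Erich5, Hjv, 2610528A11Rik, Aox2 and Lad1 had 0 in wild type and 4, 3, 2, 1 and 1 in knockout. At 2 months their log2 ratios were 3.73, 3.85, 4.72, 2.99, 2.95 and 2.40. Among lower genes, Gm16867, Gm45620, Gpr139, Dipk1c, Opn4 and Gm19689 had 11, 6, 4, 9, 2 and 2 UMIs in wild type and 0 in knockout at 1 month. At 2 months 5 of them were at -2.73 (Gm45620), -4.50 (Gpr139), -1.97 (Dipk1c), -5.05 (Opn4, the melanopsin gene) and -1.80 (Gm19689), and Gm16867 had 91 and 0 UMIs. Serpina3n and the predicted genes have close copies in the genome, and their counts are uncertain where reads could be shared.

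In all, 113 of 11911 genes were at least 2-fold higher and 41 at least 2-fold lower in knockout RPE-like cells at both ages, where independent lists would share 65.5 and 12.2. The excess of higher genes was all but gone with a 15% mitochondrial limit (98 against 95.4) and smaller with at least 1000 genes per cell (91 against 76.2). Splitting the same libraries by age gave 900 and 307 (413.6 and 89.0 from independent lists), and the crossed pairs gave 323 and 82 (348 and 124). With at least 30 UMIs required in each pair of libraries, 8 genes were higher and 8 lower out of 3631, against 0.476 and 0.481. Without the Malat1-rich cells 59 were higher and 55 lower. These 16 are named after their values were seen. The higher ones were 2900052N01Rik, Cdhr1, Hddc3, Malat1, Olfml1, Sqle, Trnp1 and Upk3b, and the lower ones Acadsb, Arl6ip1, Cox8b, Ifitm3, Krt23, Pttg1, Snhg3 and Vldlr. Cox8b, a muscle-type cytochrome c oxidase subunit, was at -1.24 and -1.13, and Ifitm3, an interferon-induced antiviral gene, at -1.06 and -1.28.

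Large ratios at a single age among genes beyond the 20 of the rule often rested on few counts. At 1 month Gm8797 (4 and 71 UMIs, 4.66), Hddc3 (13 and 51, 2.60) and 2900052N01Rik (7 and 24, 2.38) were higher in the knockout, the last 2 at both ages. Akr7a5 (34 and 5, -1.98), BC003965 (26 and 4, -1.89) and Mgst3, a microsomal glutathione transferase (29 and 5, -1.75), were lower, and at 2 months these 3 stood at 0.04, -0.16 and 0.17. At 2 months Csmd1 (5 and 106 UMIs, 5.25) and Nkain2 (8 and 56, 3.70) were higher, and Gm29823 had 0 and 63 UMIs. Csmd1 and Nkain2 are among the leading genes of the Schwann-like cluster, whose 9 and 13 cells were too few for the guard against free RNA. The hemoglobin genes Hbb-bt (1077 and 13, -5.35) and Hba-a2 (1688 and 23, -5.19), which are red blood cell genes, were lower, and Olfr570 had 32 and 0.

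Fibroblast-like cells of the knockout carried more extracellular matrix and less antigen presentation RNA at 1 month. Matrix genes had a median log2 ratio of 0.27 (25 of 34 higher, percentile 100) at 1 month and 0.09 (20 of 34 higher, percentile 98.6) at 2 months. Fn1, fibronectin, was at 1.59 and -0.24, and Timp1, a metalloproteinase inhibitor, at 0.82 and 1.72. Antigen presentation and interferon genes were at -0.49 (22 of 25 lower, percentile 0.00) and -0.15 (17 of 25 lower, percentile 2.44), with the MHC class II gene H2-Ab1 at -0.80 and -2.33. At 1 month visual cycle genes, of RPE cells, were higher in these cells too (0.54, 6 of 7 higher, percentile 99.95, with Rbp4 at 2.87), and immediate early genes were lower (-0.71, 22 of 23 lower). Pttg1 was lower here too (-3.97 and -4.71), as were Trim12a, a TRIM family gene with close copies (-4.16 and -5.33), and Plac9b (-1.72 and -2.38). Saa3, an acute-phase gene, had 5 and 0 UMIs at 1 month and 39 and 0 at 2 months. Gpha2, a glycoprotein hormone subunit gene, was at 4.47 and 3.70. Sfrp4, a secreted Wnt modulator, had 27 and 368 UMIs at 1 month (3.38) and 0 and 9 at 2 months. Kcnc2 had 1 and 12 UMIs (2.70) and then 0 and 22, and Gm35082 had 0 and 89 and then 0 and 67. Cluster 3 held most of these cells at 1 month and cluster 7 at 2 months. Cluster 24, led by collagen genes among others, held 9 of 258 wild-type and 34 of 388 knockout fibroblast-like cells at 1 month and 1 of 120 and 9 of 157 at 2 months, and this mix was not held fixed for the matrix values. Xist stood at 514.8 and 989 CPM in wild type and knockout at 1 month and at 321 and 455 CPM at 2 months.

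Macrophage-like cells of the knockout had higher lysosome and phagocytosis values, with a median of 0.55 at 1 month (13 of 14 higher, percentile 99.9) and 0.31 at 2 months (21 of 25 higher, percentile 99.9). Ctsl, a lysosomal protease, was at 1.46 and 0.58. Antigen presentation and interferon genes had lower medians (-0.33, 7 of 12 lower, percentile 1.28, and -0.38, 20 of 24 lower, percentile 0.02). H2-Aa was at -0.64 and -1.26, but H2-T23 at 1.36 and -0.18. At 2 months 11 of 11 glycolysis genes were higher (0.79, percentile 100), and Mif, a macrophage cytokine gene, was at 1.99 and 1.85. Gdpd3 had 0 and 81 UMIs at 1 month and 4 and 150 at 2 months (4.35). Cxcl14, Gpr157 and Tnfrsf21 had 0 UMIs in wild type and 5, 4 and 3 in knockout at 1 month, and were at 3.96, 2.69 and 3.54 at 2 months. Stmn1, which destabilises microtubules, was at -2.02 and -2.06, Siglece at -2.25 and -1.86, and Cd38 at -1.96 and -1.82. Trim30d had 2 and 0 UMIs and then 38 and 4 (-3.81). Immediate early genes, which dissociation induces, were far lower at 1 month (-3.23, 14 of 14 lower, with Ccn1 at 65 and 0 UMIs) and lower at 2 months (-0.37, percentile 0.04). These classes held 30 and 34 cells at 1 month, mostly in a cluster poor in Malat1 (cluster 19, median 1953 UMIs), and 56 and 55 cells at 2 months, mostly in cluster 17.

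Endothelial-like and mural-like cells could be compared at 2 months alone. In endothelial-like cells the list of activation and tip cell genes had a median of 0.24 (9 of 16 higher, percentile 98.95), with Apln, a ligand gene of sprouting vessels, at 1.62 (11 and 54 UMIs) and Pgf, placental growth factor, at 1.48 (23 and 101 UMIs). Immediate early genes were at -0.51 (16 of 21 lower, percentile 0.00). Antigen presentation and interferon genes were at -0.24 (18 of 22 lower, percentile 0.18), and all 13 mitochondrially encoded genes were lower (-0.51, percentile 0.01). In mural-like cells, the contractile cells around vessels, matrix genes were at 0.46 (22 of 28 higher, percentile 100). The activation and tip list was at 0.64 (6 of 6 measured genes higher, percentile 99.8), with Igfbp3 at 1.96. Igfbp3 is also a leading gene of the endothelial-like cluster, whose share was larger in the knockout library. RNA from that class was not tested as a source of these values. In the same mural-like cells immediate early genes were at -0.19 (13 of 20 lower, percentile 0.38) and heat shock genes at -0.29 (8 of 12 lower, percentile 0.26). Dcn, a fibroblast marker, was at 1.71 in mural-like and 2.14 in endothelial-like cells. Visual cycle genes, which mural cells should lack, were at -1.04 in mural-like cells, where all 9 measured were lower, beside the lower RPE-like share of that library.

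Between the ages, RPE-like cells had more mitochondrially encoded RNA at 2 months (median log2 ratio of 2 months to 1 month 0.66 in wild type and 0.76 in knockout, percentiles 100 and 100). Nuclear complex IV genes were lower (-0.66 and -0.59, 13 of 13 lower in both). Immediate early genes, which tissue dissociation induces, were at -1.0 in wild type (percentile 0.00) and -0.21 in knockout (percentile 11.5). Antigen presentation and interferon genes were at -0.26 and -0.86. Across genes, the ratio went with intron length (Spearman rho 0.39 in wild type over 11107 genes and 0.40 in knockout over 10228 genes, where genes are not independent replicates). Genes with over 100 kb of intron had medians of 0.92 and 0.85, and those with under 1 kb had -0.33 and -0.37. Without the Malat1-rich cluster, which held 2-month cells alone, the former were 0.47 and 0.28 and rho was 0.30 in both. The pattern was not particular to RPE-like cells. In fibroblast-like cells rho was 0.46 in wild type and 0.49 in knockout, and genes with over 100 kb of intron had medians of 0.80 and 0.82. The libraries of the 2 ages were counted with different software versions.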

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

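The difference between the ages in the fibroblast-like values was not tested, because each group was 1 library. Among the tests in this part, those of Malat1 as a cell type trait and of lost nuclear RNA were chosen only after the result was seen. The doublet test was chosen before.

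Fibroblast-like cells went in opposite directions at the 2 ages for 2 gene lists, each outside the central 95% of random lists. TGF-beta pathway genes, which govern matrix production, had a median log2 ratio of knockout to wild type of 0.13 at 1 month and -0.21 at 2 months, with Ltbp1, a TGF-beta binding protein gene, at 1.30 and -0.24. Immediate early genes, which dissociation induces, were at -0.71 (22 of 23 lower) and 0.45 (15 of 20 higher), with Fos at -0.73 and 1.89. Different clusters held most fibroblast-like cells at the 2 ages.

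Among barcodes set aside for more than 30% mitochondrial UMIs, 6 of 176 in the wild-type and 4 of 168 in the knockout library at 2 months resembled RPE cells, against 0 of 31 and 0 of 38 at 1 month.

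Most RPE-like barcodes carried little Malat1, with 80.0% of wild-type and 74.7% of knockout ones under 1000 CPM at 1 month and 89.6% and 75.4% at 2 months, against 0.00% and 1.91% of fibroblast-like and 34.0% and 47.9% of rod-like barcodes at 2 months and 73.3% and 76.5% of macrophage-like ones at 1 month. A low level as a trait of every RPE cell is at odds with 1 RPE-like cluster at 31559 CPM. Doublets with endothelial-, fibroblast-, macrophage-, mural-, rod- or surface epithelium-like cells are argued against, since markers of those classes stood at no more than 0.0020 of their level in their own class, but doublets with other classes or of RPE cells were not tested, and these cells had medians of 23039 and 27655 UMIs against 8070.5 and 9511.5 in the other RPE-like cells at 2 months. Loss of nuclear RNA from most RPE-like barcodes is consistent with the other RNAs kept in the nucleus, for which the median log2 ratio of Malat1-poor to Malat1-rich wild-type cells at 2 months was -4.92 (5 genes, Neat1, Xist, Kcnq1ot1, Airn and Ftx). Whether such cells lost their nuclei in the animal or in preparation was not tested, and the higher Malat1-rich share in the knockout stays open in the same way.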

How the results depend on the processing

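The settings that separate Malat1-rich cells, leave out clusters over 20% Gm42418 or require 30 UMIs in each pair were chosen after seeing the data, as were those removing high doublet scores, dropping Gm42418 from the scaling and leaving genes unscaled. The last 3 moved none of the main results. Of 398 main comparisons with an alternative, 355 stayed within the spread of random lists, the counting interval or 1.5 times the count, 41 moved further and 2 turned from outside the random lists to the opposite sign. Of 794 others 749, 43 and 2 did. These totals include alternatives that left values as they were. The Malat1-rich cluster held no 1-month cells to leave out, and Leiden resolution 2.0 gave the same 113 and 41 genes. A median could also stay within that spread and yet move inside the central 95% of random lists. Complex III and fatty acid oxidation at 1 month were lower in the knockout in every setting run, at -0.52 to -0.32 and -0.59 to -0.24. With a 15% mitochondrial limit the RPE-like shares at 1 month were 6.82% and 4.4%, and complexes I, IV and V were at -0.38, -0.56 and -0.51 and cholesterol synthesis at 1.15. There a cluster of 432 cells with both hemoglobin and RPE transcripts took the name of red blood cells, as a cluster of 167 cells did in the main setting. Without a limit the 2-month shares were 63.8% and 39.5%, and with at least 1000 genes per cell they were 6.65%, 3.80%, 73.6% and 51.9%. Leiden resolution 0.5 gave 53.2% for the knockout at 2 months and -0.27 for complex I at 1 month. Median-of-ratios size factors gave -0.28 for the latter. Both settings shifted the median of all genes at 1 month, to -0.14 and -0.13 from 0.00. Thinned cells gave complex IV medians of -0.12, now inside the central 95% of random lists, and -0.31, a Vldlr ratio of -3.30 at 2 months and 62 genes 2-fold higher at both ages. Equal weight per cell gave complex I at -0.20, Vldlr at -3.13 at 2 months and 74 genes lower. Without clusters over 20% Gm42418, cholesterol synthesis at 1 month was 0.12, now inside the central 95%. Subtraction of the library profile turned antigen presentation at 1 month to 0.24 and put mesenchymal transition at 2 months at 0.34, now above the central 95%. Without Malat1-rich cells, complexes I, III, IV and V at 2 months were at -0.20, -0.38, -0.35 and -0.34 and Vldlr at -3.52, with 59 genes higher. Malat1-rich cells alone gave 0.080, -0.038, -0.018 and 0.0064 for these complexes, -0.69 for mitochondrially encoded genes, 0.084 for the visual cycle, 0.47 for cholesterol synthesis and -1.65 for Vldlr, so complexes I and V and the visual cycle changed sign. Higher genes numbered 98 with the 15% limit and 91 with 1000 genes per cell, but independent lists would then share 95.4 and 76.2. At least 100 UMIs left 49 genes higher and 23 lower, 5 added counts 69 and 7, and 30 UMIs in each pair 8 and 8. These last counts follow from fewer genes measured or damped low counts. For the other settings the cause was not tested. Depth limits the 1-month RPE-like values more than the 2-month ones, since those cells held 594831 and 373506 UMIs against 15713116 and 8008785 at 2 months.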

Other observations

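Among the tests in this part, those of the mix of Malat1-rich and Malat1-poor barcodes, of short abundant transcripts at either age, of free RNA and of genome segments were chosen only after the result was seen, as was the look at chromosomes and shared genes. The test on short transcripts had been written as 1 test over both ages and was split by age after its result was seen. A test of free RNA written before the result, in which 20 of the 20 named genes stayed 2-fold apart after its subtraction, was replaced because a guard against free RNA had picked those genes.

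Several cell types showed values that the comparisons above did not reach. In endothelial-like cells at 2 months Adm, a vasodilator peptide gene induced by hypoxia, had 2 UMIs in wild type and 91 in knockout (log2 ratio 4.57), beside Bnip3 at 1.00, but the hypoxia list as a whole was at -0.09 (10 of 16 lower, percentile 10.8). Macrophage-like cells at 2 months had higher hypoxia response genes (0.87, 4 of 6 higher, percentile 100), antioxidant genes (0.35, 16 of 21 higher) and lipid handling genes (0.33, 11 of 16 higher). Spp1, osteopontin, went both ways there, at 1.94 at 1 month and -3.80 at 2 months, while Sparc, a matrix protein gene, was at 1.79 and 1.41. Cluster 19, with Spp1 among its leading genes, held 26 of 30 wild-type and 31 of 34 knockout macrophage-like cells at 1 month. At 2 months it held 11 of 56 and 4 of 55, and this mix was not held fixed. Fibroblast-like cells of the knockout had higher cholesterol synthesis genes at 1 month (0.38, 14 of 19 higher, percentile 99.9) and lower mesenchymal transition genes at 2 months (-0.26, 21 of 28 lower, percentile 0.00). C3, the central complement gene, was at -1.21 and 1.43 in them.

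Mitochondrially encoded genes had lower medians in the knockout at 2 months in fibroblast-like (-0.28), macrophage-like (-0.31), endothelial-like (-0.51), mural-like (-0.23) and Malat1-rich RPE-like cells (-0.69), each below the central 95% of random lists. In RPE-like cells as a whole the median was -0.07. In the same Malat1-rich cells complement genes were higher (0.50, 8 of 11 higher), led by the macrophage genes C1qa (0 and 39 UMIs) and C1qb (2 and 50), while C1qb went the other way in Malat1-poor cells (103 and 10). C4b was at 2.19 in all RPE-like cells. No explanation of these values was tested.

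Some genes apart at both ages in RPE-like cells were neighbours or recurred in another class. Lrit1, Cdhr1 and 2610528A11Rik, all higher in the knockout, lay side by side on chromosome 14 between 37054830 and 37114022, in a 10 Mb window with 5 such genes, against a median of 4 and an upper bound of 7 for the fullest window in random draws. Between RPE-like and fibroblast-like cells 6 genes were shared, all in the same direction, where 0.468 were expected from independent lists. These were Cdhr1, Fxyd2, Gm35082, Pttg1, Serpina3n and Trim12a. Both classes came from the same libraries, and independent lists do not allow for free RNA passing from 1 class to the other. Gm35082, Pttg1 and Trim12a passed the guard against free RNA in fibroblast-like cells. Free RNA as a source of the others there was not tested.

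The lower respiratory chain values in knockout RPE-like cells were weighed against 3 technical explanations. A different mix of Malat1-rich and Malat1-poor barcodes is argued against for complex III at 2 months, since its median was -0.38 without the Malat1-rich cells. Shares of the other RPE-like clusters differed too, and that mix was not held fixed. For scaling by Gm42418, the complex III median at 2 months was -0.24 without that locus, against -0.23 with it. Its place among random lists could not test this, since such scaling shifts all genes alike. A poorer yield of short abundant transcripts as a whole was not seen over all RPE-like cells at 2 months. There ribosomal protein genes had a median of 0.020 (45 of 80 higher). Malat1-rich cells supplied 2987695 of 15713116 wild-type and 3608392 of 8008785 knockout UMIs in that sum. The ribosomal median was not computed without them, so it cannot decide this for Malat1-poor cells, where complex III was lowest. For complex I transcript length stays open at 2 months, since random lists matched on exon length as well put it at percentile 4.21, inside the central 95%. At 1 month a poorer yield cannot be told apart from a difference in mitochondrial genes, since ribosomal protein genes were lower as well (-0.16). An effect of genotype on mitochondrial genes may add to these values as a hypothesis, but complexes I, III, IV and V lay inside the central 95% of random lists in Malat1-rich cells, and with 1 library per group it stays untested against pooling, sex and preparation.

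The genes 2-fold apart at both ages in RPE-like cells could reflect the strain around or beyond the targeted gene as well as the loss of Vldlr. Free RNA of another class stays open for part of them, since 53 of the 154 genes, but not the other 101, would need that class to supply at least 0.25 of the RNA at both ages, although 132 of the 154 stayed 2-fold apart after subtraction of an assumed profile. A variant acting in every cell type stays open: over the 6 named genes with at least 30 UMIs at an age in fibroblast-like cells the median ratio, signed by the RPE direction, was 0.89 (0.95 over 7, Cdhr1 included, with 30 UMIs over the 4 libraries), with Pttg1 (-3.97 and -4.71), Serpina3n (2.48 and 2.19) and Acadsb (-1.0 and -0.88) apart there too but not Scd1 (-0.18 and -0.27), Trnp1 (0.03 at 2 months) or Arl6ip1 at 1 month (-0.38). For Cdhr1, free RNA from RPE-like cells was not tested as a source of its fibroblast-like counts. Linkage to Vldlr also stays open, with 8 of 154 genes within 20 Mb of it against 3.30 expected, and so do genome segments, with 5 genes in the fullest 10 Mb window against a median of 4 and an upper bound of 7 in random draws. Of the 16 better counted genes, 6 lay on chromosome 7 (Acadsb, Arl6ip1, Cox8b, Ifitm3, Hddc3 and Olfml1), where 1.21 were expected. Apart from Vldlr itself, none of the 16 lay within 20 Mb of it.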
